A study of Homo sapiens with 2 samples.

How the data were processed

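Gene expression was measured on 2 Affymetrix expression arrays, 1 hybridised with RNA of QGP1 cells sorted for high aldehyde dehydrogenase (ALDH) activity and 1 with RNA of control QGP1 cells. Per the labels' protocols, the ALDH-high cells came from fluorescence-activated cell sorting, RNA was purified on columns and had an integrity number above 7 in each sample, and biotin-labelled amplified RNA was made with a kit that primes from the poly-A tail (3' in vitro transcription). Whether the control cells passed through the sorter is not given in the sources used here. The deposited values are log2 probe set levels made with RMA, per the submitters' processing notes. RMA corrects the background of the perfect-match probes, quantile-normalises the arrays to each other and summarises the probes of a probe set by median polish. Its version and the arrays that were normalised together are not given in the sources used here.

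The table held 54675 probe sets per array, of which 62 were Affymetrix controls and 54613 were compared. The array medians were 5.68 for ALDH high and 5.69 for control, and the sorted values of the arrays differed by at most 0.07. The deposited table carried no detection calls, so a dim level could not be told from absence, and a fold against a dim level is only as good as that level. A total of 16102 probe sets (29.5%) had an absolute difference that recurred, to 6 decimals, in at least 20 probe sets. These had a median level of 3.93, against 6.68 for the others, none of them was over 2-fold, and their largest difference was 0.54. Exactly equal values on both arrays were found for 2877 probe sets (5.27%).

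Gene names came from GEO's annotation of the platform, which listed 42898 of the probe sets. Of all probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none in that table, and none was named from a probe set with several. Through the Entrez ID, 41043 of the single symbols were found in a RefSeq gene table of assembly GRCh38.p14, which changed 0 of them, and 54 were kept as listed. No build is named for the array values, so no coordinates are given. For each of 19775 genes the probe set with the highest mean level of both arrays was used, a choice that does not look at the difference, and 10523 genes had more than 1 probe set. Probe sets with IDs ending in _s_at or _x_at (15499) can bind more than 1 transcript and are open to cross-hybridisation.

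With 1 array per group there is no replicate check of any difference and no test was made. The comparison is the log2 difference, ALDH high minus control, and its size as a fold. A threshold of 2-fold, the one in the series description, was applied without a filter. The differences between probe sets of one gene had a pooled SD of 0.23 over all genes with several, and 0.19 over those at or above the median level of 5.68. This spread can also hold real differences that the probe sets of a gene record unevenly. The differences of the hybridisation controls (SD 0.04 over 18 probe sets), which are added after labelling, leave out labelling error. Neither covers the spread between cultures or sorts. The number of arrays limits the precision.

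Before the data were examined, 28 gene lists with 449 different genes were fixed, of which 401 had a probe set, together with the rule for named genes. The remaining members were not analysed here. For each list except the 4 genes of the series description, which were chosen on these arrays, the median difference was set against 10000 random lists of the same size drawn from the same of 20 bins of mean level. A median below the 2.5th or above the 97.5th percentile was called apart from random lists, which is a description of these arrays. About 5% of lists drawn like the random lists lie there by chance. Members of a fixed list can be co-regulated, so this share need not hold for the fixed lists. The genes named are the 4 in the series description, the 10 with the largest difference in each direction among genes whose higher level was at or above the median, ALDH family members over 1.5-fold, and in every other list the members over 2-fold, up to 4 of them, and at least the 2 with the largest difference. A further 6 lists were chosen after seeing the data and before seeing their own values.

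Both steps were tested on simulated data made from the real levels of 19775 genes with noise of SD 0.24, in which 200 genes changed, 50 per fold size. The 2-fold threshold recovered 100% of the genes changed 4-fold, 100% of those changed 3-fold, 52% of those changed 2-fold and 6% of those changed 1.5-fold, and called 0% of the unchanged genes. Of 100 simulated lists of 18 genes with no shift, 8% were called apart, and of 100 lists shifted by 0.3, 99% were. The simulated noise was normal and independent between genes, and its SD came from these arrays, not from replicates. The real differences over probe sets had an SD of 0.32 and a 99th percentile of absolute size of 1.08. The 0% is therefore no error rate for real genes, and lists of co-regulated genes were not simulated. The alternatives were median centring, quantile normalisation, removal of a loess trend with level, a pseudocount of 32 on the linear scale, thresholds of 1.5-fold and 3-fold, a filter on dim features, leaving out shared-target probe sets, the mean or median over a gene's probe sets, the mean of a list, unmatched random lists, and lists without the genes of the series description. The mean of a list without those genes was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.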

Results

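QGP1 is an established human cell line derived from a pancreatic neuroendocrine tumour (pNET). Cells of this line with high aldehyde dehydrogenase activity, a property used to enrich for cancer stem-like cells, were profiled beside control QGP1 cells on 1 array each, to obtain the expression profile of the ALDH-high fraction. Each array gave RMA levels of 54675 probe sets. The arrays correlated at Pearson's r = 0.992 across 54613 probe sets, which are not independent replicates, and the median absolute difference was 0.16 on the log2 scale. Because each group had a single array, the differences below have no replicate check and no p-value.

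More genes were over 2-fold lower than over 2-fold higher in the ALDH-high cells. Among 19775 genes, 92 were over 2-fold higher and 243 over 2-fold lower, and at over 4-fold the counts were 14 and 26. The higher genes were led by CAV1 and KRT14 and the lower genes by INHBE and ASS1. At the level of probe sets, 220 were over 2-fold higher and 460 over 2-fold lower, 680 in all, while the series description gives 185 probe sets at this threshold, without a direction or a filter. The excess of lower values was not seen among the 11721 compared probe sets with no gene symbol, where 46 were over 2-fold higher and 40 lower. A threshold of 3-fold left 155 probe sets. Of the 60 genes over 2-fold higher that had several probe sets, all probe sets pointed the same way in 41, and in 22 another probe set was also over 2-fold. Of the corresponding 141 lower genes these numbers were 105 and 61.

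**Figure D1:**
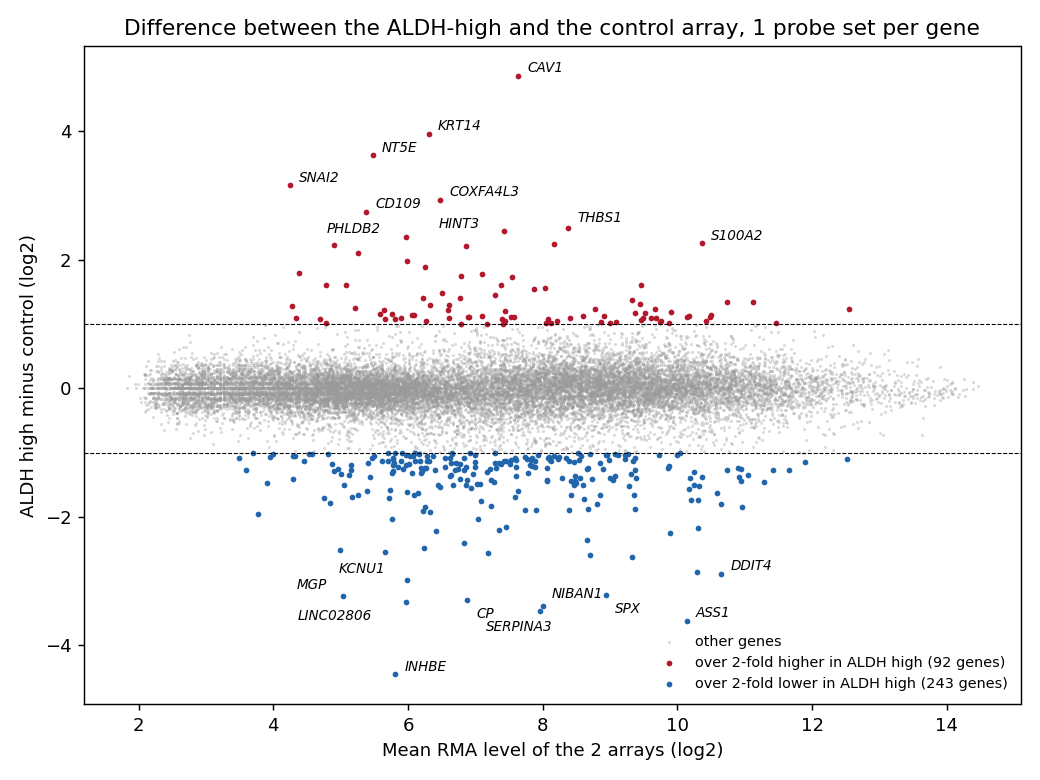
Difference between the ALDH-high and the control array (log2, vertical axis) against the mean RMA level of the 2 arrays (log2, horizontal axis), 1 point per gene and 1 array per group. Dashed lines mark 2-fold, red points are the 92 genes over 2-fold higher and blue points the 243 over 2-fold lower in ALDH high, and the labelled genes are those with the largest differences, from CAV1 at 4.86 to INHBE at -4.45.

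The 4 genes that the series description names were each among the 10 with the largest positive difference. CAV1, the main structural protein of caveolae, was 29.1-fold higher in ALDH high (10.07 against 5.21), and its second probe set differed by 5.20. NT5E, which encodes CD73, the surface enzyme that makes adenosine from AMP, was 12.3-fold higher (7.29 against 3.67). SNAI2, the transcription factor SLUG, was 8.92-fold higher (5.83 against 2.67) and CD109, a GPI-anchored surface protein, 6.73-fold higher (6.76 against 4.01). These genes were chosen on the same arrays, so their direction is not independent evidence. The large NT5E difference came from 1 of 4 probe sets, the other 3 being dim on both arrays with differences from 0.24 to 0.33. The CD109 probe sets differed by 2.75, 1.14 and 0.18, and SNAI2 had 1 probe set. As a list, the 4 genes had a median of 3.39. The control levels of SNAI2 and NT5E stood at the 5.09th and 17.6th percentiles of that array, so the size of these folds depends on a level close to the floor.

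**Figure D2:**
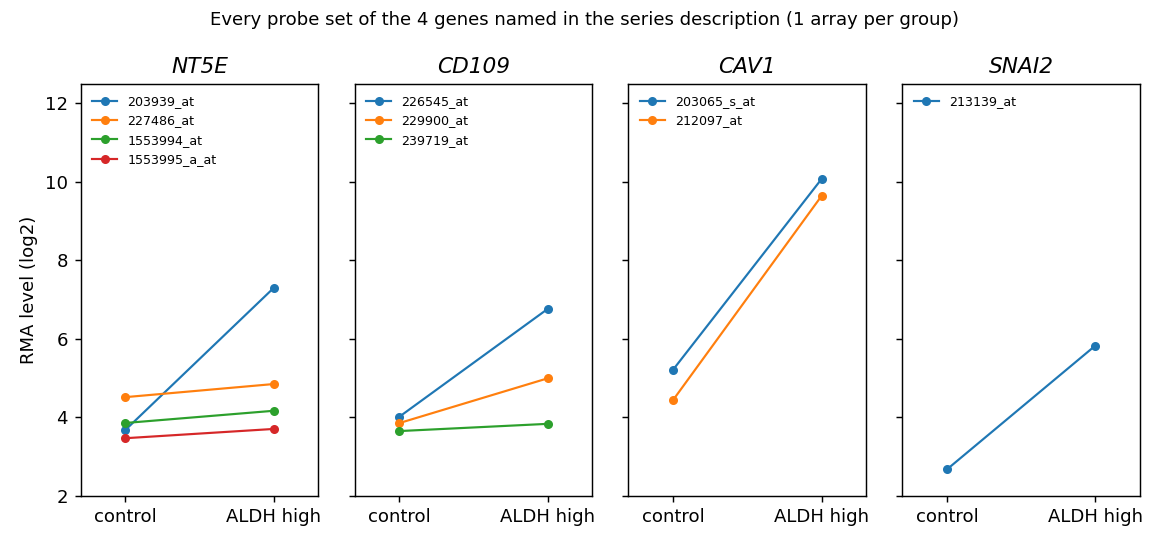
RMA level (log2, vertical axis) of every probe set of NT5E, CD109, CAV1 and SNAI2 on the control and the ALDH-high array, 1 line per probe set and 1 array per group. The CAV1 probe sets differ by 4.86 and 5.20, whereas NT5E differs by 3.62 on 1 probe set and by 0.33 or less on the other 3.

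The 10 genes with the largest positive differences held 6 further genes. KRT14, a keratin of basal epithelial cells, was 15.5-fold higher (8.29 against 4.33), and S100A2, a calcium-binding protein, was 4.77-fold higher (11.48 against 9.23). THBS1, the matrix glycoprotein thrombospondin, was 5.66-fold higher, with 4 of its 7 probe sets at 1.55 or more and the dim remainder between 0.02 and 0.07. COXFA4L3 was 7.61-fold higher on its single probe set. HINT3 (5.43-fold) and PHLDB2 (5.13-fold) rested on 1 probe set each, since their other probe sets ranged from -0.10 to 0.59 and from -0.32 to 0.29. The other PHLDB2 probe sets were dim on both arrays, with levels from 2.04 to 2.93, and could show little. Those of HINT3 were brighter (6.57 against 6.67 and 6.54 against 5.95).

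INHBE, a subunit of the activin family, was 21.8-fold lower (3.59 against 8.04). ASS1, the argininosuccinate synthase of arginine synthesis, was 12.3-fold lower (8.33 against 11.95), and DDIT4, an inhibitor of mTORC1, was 7.39-fold lower (9.21 against 12.10). The secreted protease inhibitor SERPINA3 was 11.1-fold lower, the copper carrier ceruloplasmin CP 9.79-fold lower, and the peptide hormone gene SPX 9.27-fold lower. NIBAN1 was 10.4-fold lower, with both probe sets beyond -2.6. LINC02806, a long non-coding RNA, was 9.97-fold lower, KCNU1, a potassium channel, 7.89-fold lower, and MGP, the matrix Gla protein, 9.36-fold lower. The probe sets behind CAV1, THBS1, PHLDB2, ASS1, NIBAN1, MGP and DDIT4 are open to cross-hybridisation. The other MGP probe set was equal on both arrays, at a dim level of 2.40 that could show little. The ALDH-high levels of INHBE and MGP stood at the 16.7th and 14.5th percentiles of that array, and with a pseudocount their differences were -2.74 and -1.63.

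The aldehyde dehydrogenases, the enzyme family behind the sort, did not differ in one direction. Of 19 members, ALDH1A3 was over 2-fold higher, at 3.42-fold (7.99 against 6.21), while ALDH1L2, a mitochondrial enzyme of folate metabolism, was 5.91-fold lower and ALDH2, the mitochondrial acetaldehyde dehydrogenase, 4.08-fold lower. ALDH16A1 was 1.53-fold higher and ALDH3B2 1.56-fold lower. The family's median was -0.14, at percentile 4.32 of random lists, and 15 of 19 members lay below 0. The family's mean was -0.23, at percentile 1.67 and below the bounds. ALDH1A1, named here after its value was seen because ALDH assays are often read as its activity, was 1.28-fold lower (11.78 against 12.13). The second ALDH1A3 probe set differed by 0.03 at a low level, and the mean over both was 0.90.

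Stem cell and mesenchymal lists held a few large differences among members that mostly differed little. Of 20 mesenchymal stem cell surface markers, NT5E, CD109 and the hyaluronan receptor CD44 were over 2-fold higher, BST1 was 2.43-fold lower, and the median was -0.04 (percentile 43.2). CD44 was 2.81-fold higher, with 12 of its 13 probe sets above 0 and a median over them of 0.39. Of 28 mesenchymal and EMT genes, 5 were over 2-fold higher, and CCN2 was 2.13-fold lower. The 5 were CAV1, SNAI2, THBS1, the matrix protein TNC (3.32-fold, but 0.27 as the median of its 3 probe sets) and CAV2. The other TNC probe sets were dim on both arrays (3.67 against 3.40 and 2.76 against 2.94). CAV2, named after its value was seen, was 2.02-fold higher on its main probe set, with its 3 probe sets from 0.02 to 1.01. With a pseudocount BST1 (-0.62) and CCN2 (-0.69) were no longer over 2-fold. The median of the mesenchymal and EMT genes was 0.03 (percentile 83.3), whereas their mean was 0.43, above all 10000 random lists. The mean of the mesenchymal stem cell markers was 0.24, opposite in sign to their median. Without the genes of the series description, which were chosen on these arrays, the means were 0.15 for the mesenchymal and EMT genes (percentile 99.6) and -0.08 for the mesenchymal stem cell markers (percentile 26.6). The 20 stem cell and cancer stem cell markers had CD44 as the only member over 2-fold, KIT 1.54-fold lower, and a median of 0.08 (percentile 93.6). This list lay above the bounds without shared-target probe sets (0.16) and below them with members at or above the median level (-0.22).

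Epithelial genes were nearly level between the arrays. None of 23 epithelial junction and identity genes was over 2-fold different, the median was -0.09 (percentile 6.56), and the largest differences were those of the transcription factor ELF3 (1.87-fold lower) and the keratin KRT19 (1.51-fold higher). Among 17 integrins and laminins, the laminin chain LAMB3 was 3.35-fold higher and the integrin ITGB5 2.01-fold lower, with a median of -0.08 (percentile 19.96) and a mean of 0.01. ITGB5 was no longer over 2-fold with a pseudocount (-0.93), as the mean (-0.82) or median (-0.89) of its probe sets, or without shared-target probe sets (-0.89). Of 19 targets of YAP and TAZ, NT5E and MYOF (4.66-fold, a membrane repair protein) were over 2-fold higher, and CCN2 was lower. Without shared-target probe sets MYOF stood at 0.07, on a dim probe set (5.05 against 4.99), whereas its second shared-target probe set differed by 1.59. The median of the YAP and TAZ targets was 0 (percentile 67.0). Their mean was 0.24, above the bounds, and 0.06 without NT5E, within them (percentile 88.7). In the extracellular adenosine pathway NT5E was the only one of 17 genes over 2-fold, the ectonucleotidase ENTPD2 was 1.96-fold lower, and the median was 0.10 (percentile 95.5). That list lay above the bounds with a pseudocount, without shared-target probe sets and as a mean, but its mean without NT5E was -0.09 (percentile 25.7).

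Neuroendocrine and pancreatic identity genes differed little. Of 20 neuroendocrine secretory genes none was over 2-fold different and 15 lay below 0. Their median was -0.14 (percentile 1.80), with the secreted peptide VGF 1.74-fold lower and the dopa decarboxylase DDC 1.60-fold higher, and this call ended under 4 of 10 alternatives. Among 19 islet hormones and islet transcription factors the median was 0 (percentile 59.8) with a mean of 0.08, and the median was 0.24, above the bounds, over members at or above the median level. ISL1, an islet transcription factor, was 2.36-fold higher (10.29 against 9.05) and MNX1 1.70-fold lower. Of 15 ductal markers the trefoil peptide TFF1 was 2.39-fold lower and the claudin CLDN1 2.12-fold higher, with a median of -0.09 (percentile 13.7), and CLDN1 was no longer over 2-fold with a pseudocount (0.69) or as the mean or median of its probe sets (0.81). Of 10 acinar markers none passed 2-fold, BHLHA15 was 1.80-fold lower, CPB1 was 1.35-fold higher at a low level, and the median was -0.14 (percentile 5.67). Only 1 of these acinar markers was at or above the median level, so this list could show little.

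ER stress, amino acid response and immediate early genes were lower in the ALDH-high cells. All 14 measured ER stress and amino acid response genes lay below 0, 8 of them beyond 2-fold, with a median of -1.22, a 2.33-fold lower level that was below all 10000 random lists. DDIT4 was 7.39-fold lower, TRIB3, a pseudokinase induced by ATF4, 7.26-fold lower, DDIT3, the transcription factor CHOP, 4.77-fold lower, and SESN2, a stress-induced regulator of mTORC1, 3.70-fold lower. Both probe sets of TRIB3 and of SESN2 agreed in direction and were over 2-fold. The list was uneven, so its median does not hold for every member. HSPA5 (-0.27), DNAJB9 (-0.45), SDF2L1 (-0.56) and XBP1 (-0.64), named after their values were seen, differed least. Immediate early genes had a median of -0.58, below all random lists, and 4 of 14 were over 2-fold lower, namely ATF3 (3.70-fold), EGR1 (2.56-fold), EGR3 (2.42-fold) and FOS (2.25-fold). With a pseudocount EGR3 (-0.67) and FOS (-0.97) were no longer over 2-fold. For ATF3 the probe sets ranged from -1.89 to 0.24, and their mean was -0.83.

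Inflammatory, interferon and hypoxia genes were also lower, by smaller amounts. Of 15 NF-kB and inflammatory cytokine genes 13 lay below 0 and the median was -0.46, below all random lists. PTGS2, the inducible cyclooxygenase, was 3.14-fold lower, with a second probe set at 2.97-fold. The chemokine CXCL2 was 2.21-fold lower on a probe set open to cross-hybridisation, without which its value was 0.18. That value came from a dim probe set (3.89 against 3.71), and a further dim one stood at -0.32. Of 13 interferon response genes 12 lay below 0, the antiviral gene MX1 differed by -1.32 on the log2 scale (-0.83 with a pseudocount) and IFIT1 by -0.997, and the median was -0.30 (percentile 0.05). Of 13 hypoxia response genes the angiogenic factor VEGFA (2.62-fold), NDRG1 (2.35-fold) and PDK1, which restrains pyruvate oxidation (2.16-fold), were over 2-fold lower, and the median was -0.22 (percentile 0.96). The hypoxia call ended when shared-target probe sets were left out, and PDK1 differed by -0.60 as the mean of its probe sets.

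Cell cycle genes were higher in the ALDH-high cells. All 20 G2 and M phase genes lay above 0, with a median of 0.81, a 1.76-fold higher level above all 10000 random lists. Of these 5 were over 2-fold higher, among them CDC20, the activator of the anaphase-promoting complex (2.55-fold), the mitotic kinesin KIF20A (2.48-fold), the mitotic kinase AURKA (2.17-fold) and cyclin CCNB1 (2.03-fold). All 17 S phase genes lay above 0 as well, with a median of 0.54, above all random lists. TYMS, the thymidylate synthase, was 2.54-fold higher on its main probe set, with the others down to 0.88, and GINS2, a replication factor, was 1.76-fold higher. On the probe set left when shared targets were left out, AURKA differed by 0.14 and CCNB1 by 0.89, and as the mean of their probe sets by 0.77 and 0.96. That AURKA probe set was dim on both arrays (5.15 against 5.01), whereas its brighter probe sets differed by 1.12 and 1.06.

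Cholesterol synthesis and heat shock genes were also higher in the ALDH-high cells. All 10 measured cholesterol synthesis genes lay above 0, with a median of 0.58, above all random lists, and none was over 2-fold. IDI1, the isopentenyl diphosphate isomerase, was 1.85-fold higher and SQLE, the squalene epoxidase, 1.77-fold higher. Of 9 heat shock genes 8 lay above 0 and the median was 0.45 (percentile 99.99). The chaperone HSPH1 was 1.97-fold higher, with all 3 probe sets between 0.98 and 1.08, whereas HSPA6 was 2.42-fold lower, but -0.92 on the log2 scale with a pseudocount.

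Other lists did not stand apart. The median of 13 NRF2 targets was 0.04 (percentile 74.9) with a mean of -0.03, AKR1B10 being 1.60-fold higher at a low level and SRXN1 1.53-fold lower. Of 9 drug efflux transporters ABCC3 was 2.36-fold lower and ABCC5 differed by 0.58 on the log2 scale, with a median of -0.14 (percentile 7.02). ABCC3 differed by -0.06 on the probe set left when shared targets were left out (5.88 against 5.94). The other shared-target probe sets of ABCC3 differed by -0.83, -0.60 and 0. The 12 cytosolic ribosomal protein genes had a median of -0.09 (percentile 13.2), with RPL3 at 1.19-fold and RPS6 at 1.15-fold lower.

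Markers of other cell types gave no sign of a shift between the arrays as lists, but most were dim, so the lists could show little. At or above the median level were 5 of 14 fibroblast and stellate cell, 2 of 10 endothelial and 2 of 10 leukocyte markers. The 14 fibroblast and stellate cell markers had a median of -0.09 (percentile 15.1), with FAP 1.35-fold and ACTA2 1.34-fold lower. The 10 endothelial markers had a median of -0.01 (percentile 56.5) and a mean of 0.06, with ESAM and ROBO4 each at 0.37 on the log2 scale. The 10 leukocyte markers had a median of -0.03 (percentile 49.8), with LYZ 2.52-fold and CD14 2.03-fold lower, both at low levels. With a pseudocount they were no longer over 2-fold (-0.67 and -0.48), and LYZ stood at -0.42 without shared-target probe sets. As signs of RNA quality, the 3' probe set of ACTB exceeded the 5' probe set 1.83-fold on the ALDH-high and 1.67-fold on the control array, and that of GAPDH 1.14-fold and 1.15-fold. The hybridisation controls differed by 0.05 on average (SD 0.04 over 18 probe sets) and the poly-A controls by 0.32 (SD 0.07 over 24 probe sets). Among the genes named from the lists, those measured on probe sets open to cross-hybridisation were ABCC3, ABCC5, AKR1B10, ALDH3B2, ATF3, AURKA, CAV2, CCNB1, CDC20, CXCL2, DNAJB9, EGR1, ELF3, FAP, GINS2, HSPH1, IDI1, ITGB5, KIT, LYZ, MYOF, NDRG1, ROBO4, RPL3, RPS6, SDF2L1, SESN2, VEGFA and VGF.

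**Figure D3:**
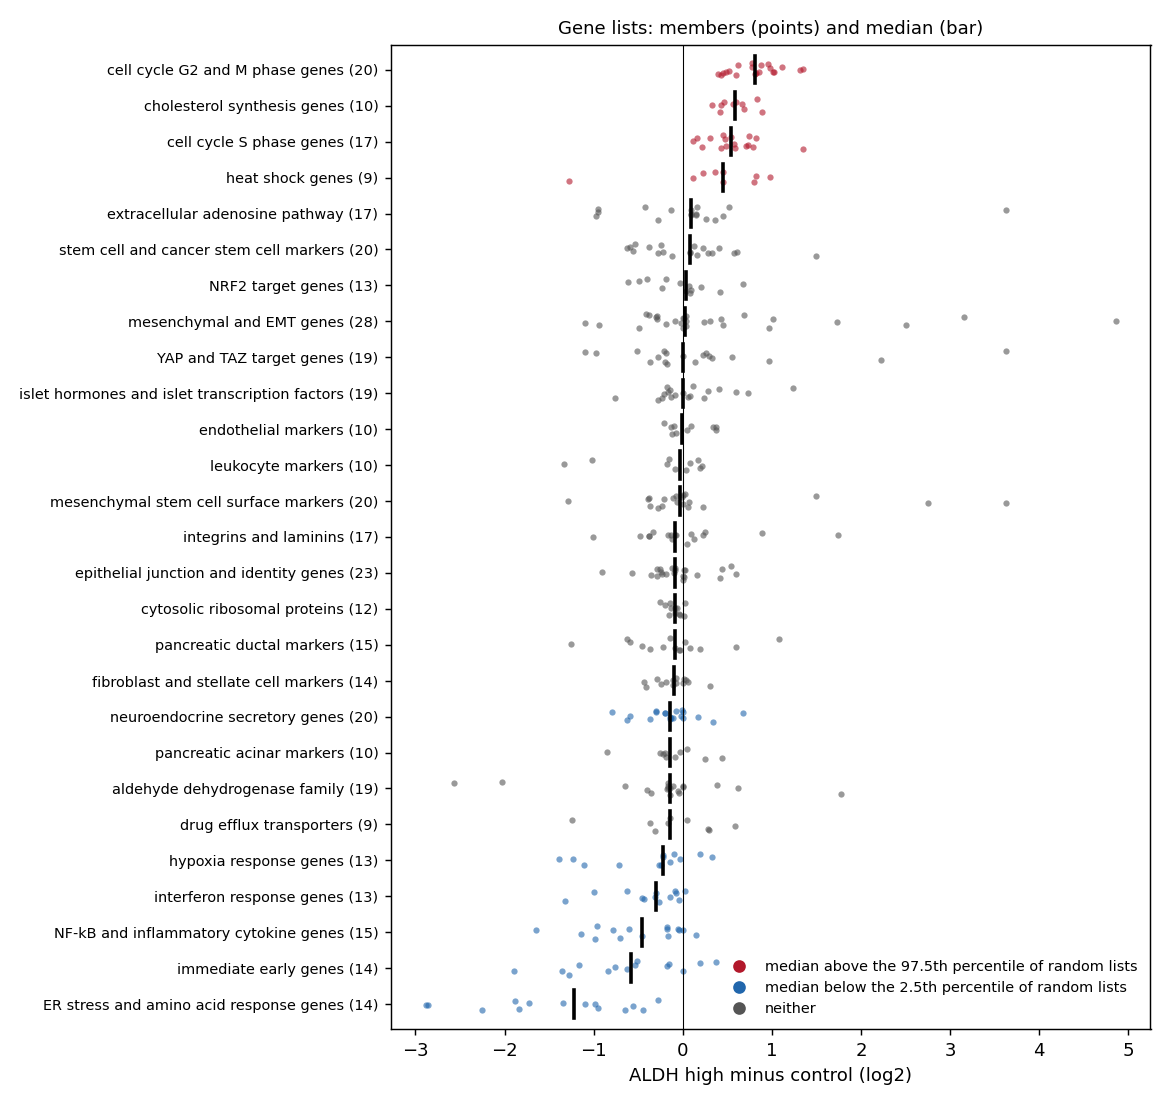
Difference between ALDH high and control (log2, horizontal axis) of the measured members of 27 gene lists, 1 point per gene with the number of genes in parentheses, 1 array per group. Black bars are medians, and colours mark lists whose median lay above (red) or below (blue) the central 95% of 10000 level-matched random lists, from G2 and M phase genes at 0.81 to ER stress and amino acid response genes at -1.22.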

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

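The tests on the poly-A controls and on drift with level were chosen only after the results were seen. The other tests in this part were written down before their values were seen, on patterns that had been noticed in the same arrays.

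The poly-A controls, bacterial RNAs added to each sample before labelling and not part of the comparison of genes, were higher on the ALDH-high array, by a median of 0.34 over 24 probe sets (1.27-fold). They stand out because the hybridisation controls, added after labelling, differed by a median of 0.052. Brightness that normalisation left would raise both kinds of control, which argues against a brighter hybridisation or scan as the cause of the excess. The lowest mean among the 4 poly-A species was 0.23, for dap with probe sets from 0.11 to 0.35, while single hybridisation control probe sets reached 0.13. A candidate explanation is less cell RNA per added control RNA in the ALDH-high sample, but RNA amounts were not given in the sources used here, and no biological explanation was tested.

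The ER stress and amino acid response genes, with a median of -1.22, kept a median of -0.80 over the 10 genes left without shared-target probe sets, below all random lists, which argues against cross-hybridisation as the whole cause. Level-matched random lists had a median of 0.0033, which the quantile normalisation in RMA places near 0 in advance. No drift shared by genes of the same level was thus left in these values. Whether one was present before normalisation cannot be told from this median. Loss of short-lived transcripts during sorting was set against 22 transcripts of ATF4 targets taken to be long-lived (tRNA synthetases, serine and one-carbon enzymes and transporters, their half-lives not measured here). All 22 lay below 0 with a median of -0.65, CBS, PHGDH, WARS1 and SARS1 being over 2-fold lower, so decay of short-lived transcripts is unlikely to be the whole cause. A general fall of short-lived transcripts stays open, since 22 short-lived regulators outside these lists had a median of -0.12 (percentile 2.98), as do the ALDH state itself, the sort and the culture of the control cells, which 1 array per group cannot separate.

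The cell cycle genes had a median of 0.71 over 37 genes of both lists, all 37 of them higher in ALDH high. The median was 0.62 over 29 genes without shared-target probe sets, which argues against cross-hybridisation as the whole cause. Level-matched random lists had a median of 0.0074, which is likewise near 0 through the normalisation and cannot tell of drift before it. As a hypothesis, a larger share of cycling cells in the ALDH-high sample predicts that other mitosis genes are higher too. All 24 further mitosis genes were, with a median of 0.68, ANLN, DLGAP5 and KIF23 being over 2-fold higher, but genes of the same programme cannot tell a larger share of cycling cells from a higher level per cell. Both stay open, as do the ALDH state, the gate and the culture of the control cells, which were not tested.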

How the results depend on the processing

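The mean of a list without the genes of the series description was chosen after seeing the data. No replicate could be left out and no paired analysis was possible because each group has 1 array. Centring, quantile normalisation and loess left all 55 named genes that were over 2-fold on that side, and moved the median of all differences by less than 0.01. The values were already quantile-normalised by RMA, so these settings could change little. No difference changed by more than 0.07 under them, and dependence on the normalisation itself was not tested. For higher and lower probe sets (220 and 460), the pseudocount gave 89 and 209, a 1.5-fold threshold 1518 and 1686, and a 3-fold threshold 43 and 112. For genes (92 and 243) these were 50 and 127, 516 and 833, and 24 and 58, and the mean or median over a gene's probe sets gave 56 or 55 higher genes. The pseudocount, which shrinks dim probe sets by construction, lowered CAV1 to 4.004, NT5E to 2.08, CD109 to 1.54 and SNAI2 to 1.21, and without shared-target probe sets CAV1 was 5.20. The mean over probe sets gave 1.13 for NT5E and 1.36 for CD109, and the median 0.32 for NT5E, no longer over 2-fold, and 1.14 for CD109, since their dim probe sets then count. Among named genes over 2-fold, 1 value changed sign, CXCL2 at 0.18 without shared-target probe sets, on a dim probe set (3.89 against 3.71). Over all named genes 116 of 546 values moved by more than 0.23, and the genes no longer over 2-fold were 10 of 55 with the pseudocount, 14 of 55 by the mean and 14 of 55 by the median over probe sets, and 10 of 47 without shared-target probe sets. Of the 275 list values 39 moved, and no list called apart from random lists changed sign, though lists within the bounds did. With members at or above the median level, the medians were -0.11 for mesenchymal stem cell markers, 0.23 for mesenchymal and EMT genes (percentile 99.83, now apart), -0.22 for stem cell markers (percentile 1.05, now below) and 0.24 for islet genes (percentile 98.54, now above). Means in place of medians were 0.24 for mesenchymal stem cell markers and 0.43 for mesenchymal and EMT genes (both now above, but -0.08, within the bounds, and 0.15, still above, without the genes of the series description), -0.23 for the ALDH family (percentile 1.67, now below) and 0.082 for islet genes. YAP and TAZ targets (0.24) and adenosine genes (0.13) were also above as means, but not without NT5E. Stem cell markers without shared-target probe sets stood at 0.16 (percentile 98.54, now above), so this list changed side with the setting. The neuroendocrine call ended under loess, without shared-target probe sets, with the mean and with unmatched lists. The calls of the cell cycle, cholesterol, heat shock, ER stress, immediate early, NF-kB and interferon lists held in all 10 alternatives each. Among these, centring, quantile normalisation and loess could change little. The cause of the other changes was not tested. Dim levels limit all folds against them.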

Other observations

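Each test in this part was written down before its value was seen, on patterns noticed in the same arrays, and the genes named in this part were chosen after their values were seen.

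Outside the lists fixed at the start, several single genes were over 2-fold higher in the ALDH-high cells. ANXA1, a calcium-dependent membrane-binding protein, differed by 2.25 on the log2 scale (and by 0 on its other probe set), the gap junction protein GJA1 by 2.22, the endothelial lipase LIPG by 1.99, the adhesion protein FLRT2 by 1.88 (down to 0.33 on others), and FGFBP1, which releases fibroblast growth factors, by 1.61. PLAU, the urokinase plasminogen activator, differed by 1.56, and by 1.25 on its other probe set. Other single genes were over 2-fold lower. The glycoprotein hormones STC1 and STC2 differed by -2.62 and -2.36, each in the same direction on every probe set. The disulfide isomerase family members AGR2 and AGR3 differed by -1.85 and -2.52, and LCN2, an iron-siderophore carrier, by -2.41.

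The higher KRT14, S100A2 and LAMB3 raised the hypothesis that a wider basal epithelial programme is higher. The median of 13 other basal genes was 0.057 (percentile 85.9), which would have gone against it by the bound written down beforehand. That bound was wrong for members that go both ways, 7 above and 6 below 0 and only 6 at or above the median level, so the hypothesis stays undecided. SFN, KRT16 and KRT5 stood at 0.97, 0.97 and 0.88 and KRT15 at -1.14. The lower SERPINA3, AGR2 and LCN2 raised the hypothesis of a wider lower mucosal secretory programme. Its 20 further genes had a median of -0.13 (percentile 4.68), which leaves it undecided, with 14 below 0 and CEACAM1 at -0.87. The higher CAV1 and CAV2 raised the hypothesis that caveola coat genes are higher with CAV1. Their median was -0.18 over 7 genes (percentile 7.17, within the bounds). CAVIN1 stood at -0.18, EHD2 at -0.27, PACSIN2 at -0.68, PACSIN3 at -0.60 and CAV3 at 0.02. The median goes against a rise of this set on the main probe sets only. CAVIN2 and CAVIN3 were dim on both arrays. Other probe sets of CAVIN1, EHD2 and PACSIN2 reached 0.25, 0.14 and 0.24, so single members stay undecided.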
